A study of Mus musculus with 8 samples.

How the data were processed

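Expression was measured in mouse small-intestinal organoids, which are crypt-like epithelial structures grown in culture, on 8 Agilent 4x44K mouse arrays with 2 colours. Each array carried RNA from 1 organoid culture (its own RNA) and RNA from a control culture, labelled with Cy5 and Cy3. Per the labels' protocols, 500 ng of total RNA was labelled with a Quick Amp kit, and all organoids received a 16 h pulse of 4OH-tamoxifen, the ligand that activates CreERT2. The labels give 24 h until RNA extraction for the Ascl2-overexpressing organoids of experiment 1, and no such time was used for the other experiments.

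The arrays fall into 3 experiments, each on a slide and a scan day of its own. Experiment 1 held 2 arrays of Ascl2-overexpressing organoids against VillinCreERT2 organoids, with the dyes swapped on replicate 2. Experiment 2 held 1 array each of Tcf7l2 null organoids, Tcf7l2 null organoids overexpressing Ascl2, and Ascl2-overexpressing organoids, all with Cy5 for their own RNA against organoids transduced with dsGFP, and 1 self-self array with dsGFP RNA in both channels. Experiment 3 held 1 array of Ascl2 null organoids against VillinCreERT2 organoids and 1 self-self array of the control. A self-self array carries the same RNA in both colours and measures dye bias and technical spread. For the experiment 3 control, the genotype field and the description differ in the labels, and the genotype field was used.

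The deposited scanner files hold spot intensities for 45018 spots per array, of which 1639 are controls. Per the file headers they were made with Agilent Feature Extraction 10.5.1.1. The median spot and local background intensity of each channel were used, because the 6 files of experiments 2 and 3 hold no mean spot intensity, which had been planned. The log10 ratio in those files is Cy5 over Cy3 after Feature Extraction's own background and dye correction, per the file headers, and was an alternative. The authors' deposited value table holds log2 ratios. On the 6 arrays of experiments 2 and 3 they have the scale of the scanner ratios, Cy5 over Cy3, with no further centring. Replicate 2 of experiment 1 is turned. On the experiment 1 arrays, 8.71% and 8.50% of the table's values differed from the scanner ratio of the same spot by more than 0.02. Over all values of these arrays the correlations with the scanner ratio were 0.86 and 0.83, and the slopes 0.86 and 0.83. Why they differ is not given in the sources used here. The table's medians per array, as deposited, were 0.02 and -0.01 in experiment 1, 0.02 for the dsGFP self-self array, 0.00 for Tcf7l2 null, 0.03 for Tcf7l2 null with Ascl2 overexpression, and 0.00 for the remaining 3 arrays. No per-sample column was left without a sample.

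Background was corrected with normexp (offset 50), and Cy5 over Cy3 log2 ratios were normalised by loess within each array, with controls and outlier spots at weight 0 (R 4.3.3 with limma 3.58.1). Outlier spots were then left out and spots of a probe averaged. Loess sets most genes near 0 on every array, so a change of all genes in the same direction cannot be seen. Of 41174 probes, 27621 were kept because a channel was well above background on at least 2 of the 8 arrays. Through RefSeq's gene table for the assembly GRCm38.p6, 26918 probes were named by their own transcript accession and 95 by another listed accession, while 14161 kept the name in the array's own, older annotation. The brightest probe stood for each of 19339 genes, of which 14837 have a plain current symbol. Coordinates are those of the array's mm9 annotation; exons and untranslated regions were not analysed here. No spot was saturated, and the number of arrays limits the precision. The share of spots well above background ranged from 50.1% to 61.1% in Cy3 and from 53.8% to 67.4% in Cy5.

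A limma model over all 8 arrays held a dye term, an Ascl2 overexpression effect shared by 3 arrays, and an effect for each of the remaining 3 conditions. It leaves 3 residual degrees of freedom. P-values are two-sided, with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. A model with an Ascl2 effect per experiment tested the difference, experiment 2 minus experiment 1. It leaves 2 residual degrees of freedom, from the dye swap of experiment 1 and the self-self arrays, so it sets the single array of experiment 2 against technical spread and does not measure the spread between cultures. Values given for experiment 1 or 2 come from this model unless said otherwise, and those of the conditions with 1 array from the first. A self-self value is that array's ratio less the dye term estimated without it. The labels do not say that the replicates of experiment 1 came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Conditions with 1 array have no replicate check, and no p-value is given for them. Genes at or beyond 2-fold are counted beside the same count on the self-self arrays. A limma test with pooled spread, run as an alternative, sets such an array against the spread of the Ascl2 overexpression and self-self arrays. Where a channel was not well above background, a bound is given as "at least N-fold", the brighter channel's normalised level against the higher of the dimmer channel's level and the lowest level among probes well above background; such bounds come before the dye term, are open to dye bias, and are given as bounds only where the ratio after the dye term was not smaller.

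The common Ascl2 effect lets genes that moved in opposite directions in experiments 1 and 2 shift the dye term, by up to 0.71 on the log2 scale. In 11 genes the shift was above 0.5, and it was above 0.3 in 48 of the 81 genes that passed the test of the difference. The values of such genes on the arrays without a replicate move by the same amount, so the dye term of the model with separate effects was added as an alternative after the data were seen.

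The 18 gene lists and the rule for named genes were fixed before the data were examined: CBC (crypt base columnar) stem cell, Wnt/beta-catenin target, position 4 and quiescent stem cell, Paneth, goblet, enteroendocrine, tuft, enterocyte, cell cycle, Notch pathway, interferon response, p53 and stress, cholesterol synthesis, fetal and regenerative epithelium, mesenchymal, immune, erythrocyte and endothelial, and MHC class II and antigen presentation. Lists were tested for Ascl2 overexpression with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation camera has only the residual degrees of freedom, 3 for the common effect and 2 for the difference. A list can fail that version for this reason alone. On conditions with 1 array a list's median is given with its percentile among 10000 random lists of the same size, matched on intensity in 20 bins, as a description of these arrays. For Ascl2 overexpression the named genes are the 10 highest and 10 lowest changes past the threshold with the same sign on all 3 arrays, filled by the size of the moderated statistic. For each condition with 1 array they are the 10 highest and 10 lowest ratios among genes whose brighter channel was well above background and whose self-self values lay within 0.5 of 0. Ascl2, Tcf7l2, Lgr5, CBC members and up to 2 highest and 2 lowest members of a list were also named. Some genes that the rule names are not reported here.

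The model, the 2-fold count, the list percentile and camera with the preset correlation were tested on simulated gene ratios. These were built from the real dye terms and spreads of 19077 genes, with 200 genes changed and the CBC list shifted by 0.5. Background correction, loess, fry, the estimated correlation and the bounds were not tested in this way. For Ascl2 overexpression the model called 74.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 12 false calls. The simulated changes were the same on all 3 arrays, and the spreads were those the model had already moderated. These shares therefore do not say how many real 2-fold changes the model would miss. In the real data, genes with a common effect beyond 2-fold did not pass. For the conditions with 1 array, 52.2% of genes changed 2-fold and 100% of those changed 4-fold passed the 2-fold limit, beside a mean of 63 unchanged genes. Alternatives were the normexp offset, the scanner's log ratio, median centring, the filter on dim probes, the dye term, the mean of all probes of a gene, the authors' table, the replicates, the self-self arrays and the thresholds.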

Results

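Gene expression was compared between genetically modified and control mouse small-intestinal organoids to ask how Ascl2, a basic helix-loop-helix transcription factor of crypt stem cells, and Tcf7l2, the DNA-binding partner of beta-catenin in the Wnt pathway, shape the crypt programme. Overexpression of Ascl2 was measured on 3 arrays in 2 experiments. Loss of Tcf7l2, loss of Tcf7l2 combined with Ascl2 overexpression, and loss of Ascl2 were each measured on 1 array, and 2 self-self arrays gave the technical background. All values below are log2 ratios of an array's own RNA over its control, over 19339 genes.

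The targeted genes were examined first. The single Ascl2 probe (mm9 chromosome 7, 150154439 to 150154498) was well above background on all 8 arrays. It was not higher on any array labelled as overexpressing Ascl2: -0.15 in experiment 1, -0.53 in experiment 2 and -0.73 in Tcf7l2 null organoids with Ascl2 overexpression. On the array labelled Ascl2 null it was -0.87, and on the Tcf7l2 null array -0.37. The brightest Tcf7l2 probe (chromosome 19, 56007586 to 56007645) was -0.39 on the Tcf7l2 null array and 0.13 on the array labelled Tcf7l2 null with Ascl2 overexpression. The self-self arrays gave 0.42 and -0.49. On the Ascl2 overexpression array of experiment 2 this probe was 0.02, from the model with separate effects. With the dye term of the model with separate effects, the 2 dimmer Tcf7l2 probes were -0.16 and -0.24 on the Tcf7l2 null array, -0.20 and -0.26 with Ascl2 overexpression added, and -0.07 and 0.09 on the Ascl2 overexpression array of experiment 2. Their self-self ratios, before the dye term, ran from -0.20 to 0.32. Which parts of Ascl2 the overexpression construct carries, and which parts of the genes were deleted, is not given in the sources used here, so these probes do not check the labels. Conditions are therefore named by the array labels throughout, and every direction below rests on those labels.

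In organoids labelled as overexpressing Ascl2, genes of mature absorptive cells were lower as a list by camera's preset correlation (adjusted p = 0.0573 with an estimated correlation), and no gene passed the test over all genes. The enterocyte list had a median of -0.50, and 26 of its 28 measured members were below 0. Lactase (Lct) was -1.21 ± 0.14 (SE, n = 3) and the drug-metabolising enzyme Cyp3a11 -1.22 ± 0.24. The antimicrobial lectin Reg3g, listed with the enterocyte genes, went the other way at 1.27 ± 0.10.

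Among single genes, the keratins Krt18 and Krt7 were 1.21 and 0.89, the ribosomal protein genes Rplp0 and Rpl17 were 0.65 and 0.69, and the non-coding RNA Gas5 was 0.71. Tspan1 (0.94), Cyba (0.76), Rangrf (0.80) and Cotl1 (0.76) completed the genes with the strongest statistic and a higher level. The actin-severing protein Scin had -1.50, and the actin bundler Pls1 -0.96. The sugar transporter Slc5a11 (-0.90), the non-coding RNA Neat1 (-0.87), Vwce (-0.76), Cyp2c55 (-0.73), Rgn (-0.71) and the glycolytic regulator Pfkfb4 (-0.68) were also lower. None of these passed, the smallest adjusted p being 0.096 for Krt18 and Reg3g.

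With limma, 0 genes passed at an adjusted p under 0.05, and 1325 had an unadjusted p under 0.05, 593 higher and 732 lower. Within experiment 1 alone 0 genes passed and 1504 had an unadjusted p under 0.05; a dye term per slide also gave 0 genes. Camera with the preset correlation called 4 of the 18 lists, none of which held with an estimated correlation. That version has 3 degrees of freedom, so such a failure need not come from correlation between genes. The estimated correlation of the enterocyte list was 0.013, near the preset, and that of the Paneth list 0.68. Fry, which tests whether the genes of a list move on balance in the same direction without comparing them with other genes, called the enterocyte list alone. The enterocyte list was lower (adjusted p = 7.56e-18; adjusted p = 0.0573 with an estimated correlation; fry adjusted p = 0.0254), with 15 members lower and 1 higher when adjusted over the list alone and 0 over all genes. The fetal and regenerative epithelium list was higher, with a median of 0.39 (adjusted p = 7.31e-05; adjusted p = 0.212 with an estimated correlation) and 3 members passing when adjusted over the list alone; Krt7 (0.89) and Clu (0.72) were its highest members. Its median was 0.17 in experiment 1 and 0.83 on the single array of experiment 2. Paneth genes had a median of -0.24 (adjusted p = 0.0421; adjusted p = 0.764 with an estimated correlation), and Notch pathway genes one of 0.11 (adjusted p = 0.0284; adjusted p = 0.655 with an estimated correlation), in both lists with 0 members passing when adjusted over the list alone or over all genes. The Paneth value rests on the array of experiment 2, with a median of -1.14, against 0.08 and 13 of 16 members above 0 in experiment 1; the Notch medians were 0.01 and 0.14. Among goblet genes 3 were higher and 1 lower when adjusted over the list alone and 0 over all genes.

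For the CBC stem cell list the overexpression arrays of the 2 experiments lay on opposite sides of 0. Its median was 0.36 in experiment 1, with 18 of 23 members above 0, and -0.53 in experiment 2, with 21 of 23 below. With the dye term shared by all arrays, the medians of replicates 1 and 2 of experiment 1 were 0.51 and 0.05. Lgr5, the R-spondin receptor that marks these stem cells, was 0.55 ± 0.12 (SE, n = 2) in experiment 1 and -2.11 in experiment 2. Olfm4, another stem cell marker, was 0.89 and -2.06, Cdca7 0.46 and -1.33, and Axin2, a Wnt feedback gene, 0.36 and -1.12. The enteroendocrine list had medians of -0.20 and 0.06, the latter within the range of random lists, and its members went both ways. Among them Gcg (proglucagon) was -0.90 and 4.09, Gip -0.99 and 3.79, Sst (somatostatin) -0.92 and 3.35, and Cck -1.08 and 3.14, whereas Sct (secretin) was -0.96 and -0.46. Sst and Sct were named after their values were seen. Enterocyte genes had medians of -0.53 and -0.55.

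The difference between the experiments was set against the spread of the experiment 1 dye swap and the self-self arrays, with 2 residual degrees of freedom, and experiment 2 gave 1 array. The p-values that follow therefore compare that array with technical spread and cannot show that the experiments differed beyond the spread between cultures. On these terms 81 genes passed, 49 higher and 32 lower in experiment 2, among them Lgr5 (adjusted p = 0.0134), Gcg, Gip and Cck (adjusted p = 0.00332 each) and Sst (adjusted p = 0.0181). Median centring in place of loess ended all of these calls, the scanner's log ratio gave 71 higher and 26 lower, with 50 of the 81 among them, and the authors' values gave 111 and 35, with 65 among them. Camera called the difference of the CBC list (adjusted p = 4.14e-14; adjusted p = 0.223 with an estimated correlation), with 12 members lower when adjusted over the list alone and 1 over all genes. It also called that of the enteroendocrine list (adjusted p = 1.16e-06; adjusted p = 0.223 with an estimated correlation), with 7 members higher and 1 lower when adjusted over the list alone and 4 higher over all genes. Over all genes the correlation of the experiments was 0.02; a dye term per slide gave 0.16. Genes are not independent replicates, and correlations across genes were computed for 10 pairs of conditions under 4 dye treatments.

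**Figure D1:**
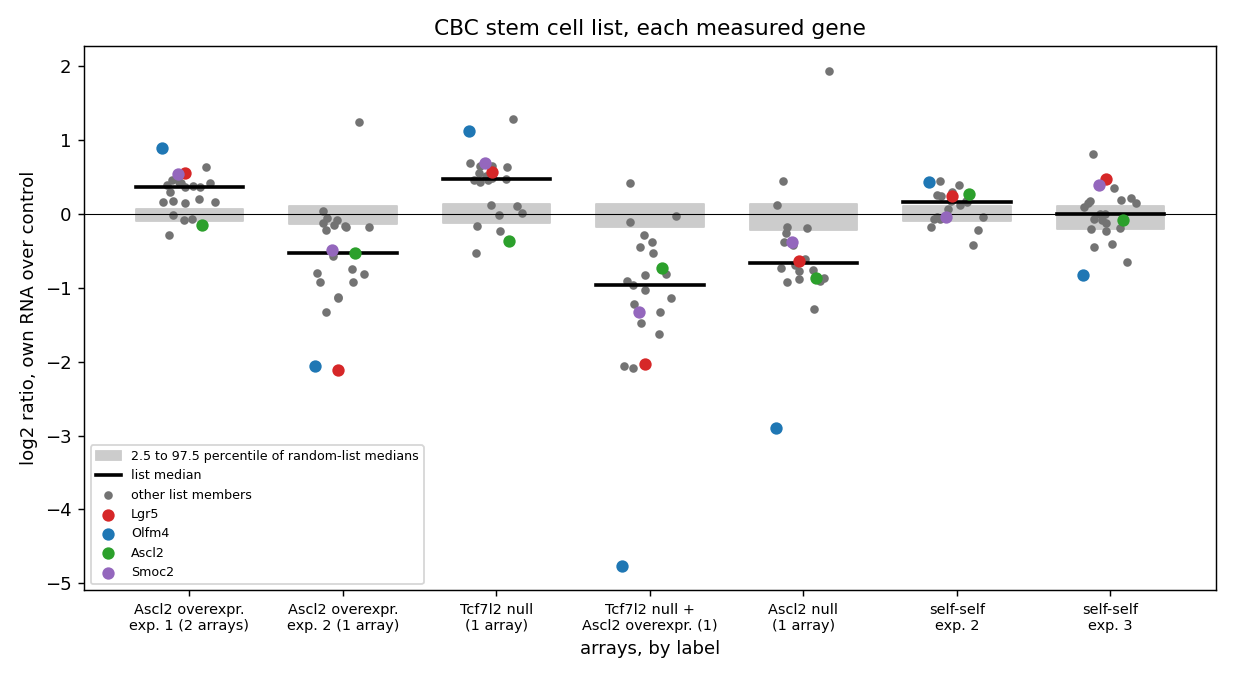
Log2 ratio of own RNA over control (vertical axis) for each measured gene of the CBC stem cell list, by array label (horizontal axis). Black bars are list medians, grey bands the central range of random-list medians, and points single genes, with 4 coloured; the medians lie at 0.36 for Ascl2 overexpression in experiment 1 and at -0.53, 0.47, -0.96 and -0.66 for the next 4 labels, the experiment 1 and 2 overexpression values coming from the model with separate effects.

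On the array labelled Tcf7l2 null, cell cycle and stem cell genes were higher and enterocyte genes lower than in the dsGFP control. All 30 measured cell cycle genes were above 0, with a median of 0.54; the replication helicase subunits Mcm6 and Mcm7 were 0.81 and 0.79. The CBC list had a median of 0.47, with Aqp4 at 1.29, Olfm4 at 1.13 and Lgr5 at 0.57, and Wnt targets one of 0.25, with Apcdd1 at 1.61. The enterocyte median was -0.57, with Fabp1, a fatty acid binding protein, at -1.22 and Cyp3a11 at -0.97. All 4 medians lay outside the range of random lists, but on the self-self array of the same slide the CBC (0.16), Wnt target (0.18) and enterocyte (-0.10) medians did so too.

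The highest named ratios were those of Ctrb1 (chymotrypsinogen, 2.16), Krt18 (1.61), the scavenger receptor Olr1 (1.58), the linker histone H1f5, Epdr1 (1.49), Depp1 (1.41), lamin Lmnb1 (1.40), Myh7 (1.30), Dmpk (1.29) and the actin-binding peptide gene Tmsb4x (1.29). The lowest were Me1 (malic enzyme, -2.12), Slc5a4b (-1.48), Pou5f2 (-1.39), Pfkfb4 (-1.38), the brush-border dipeptidase Dpep1 (-1.35), the nucleoside transporter Slc28a3 (-1.29), the glucuronosyltransferase Ugt1a9 (-1.29), ceramidase Asah2 (-1.27), the cholesterol exporter Abca1 (-1.25) and Fabp1 (-1.22). Notch pathway genes (0.23), fetal and regenerative genes (0.29) and p53 and stress genes (0.17) had medians above the random range. Medians within it were those of position 4 genes (0.17), goblet (-0.10), enteroendocrine (-0.01), tuft (-0.07), interferon response (0.02) and cholesterol synthesis genes (-0.12); the Paneth median of -0.15 lay at its lower edge.

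In total 114 genes were at or beyond 2-fold, 56 higher and 58 lower, beside 11 and 82 on the self-self arrays of experiments 2 and 3. With the dye term of the model with separate effects, the CBC median was 0.30, Lgr5 0.19 and Olfm4 0.70, and the scanner's log ratio gave 1442 genes beside 720 and 1157 on the self-self arrays. Median centring gave 91 higher and 55 lower. Across genes this array correlated with Ascl2 overexpression in experiment 1 (r = 0.58, and 0.49 to 0.58 over the 4 dye treatments). With the array labelled Ascl2 overexpression of its own experiment r was 0.19, and 0.19 to 0.42 over these treatments, beside simulated values of 0.05 and 0.49 for unchanged genes with a shared control.

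Tcf7l2 null organoids with Ascl2 overexpression had lower stem cell, Paneth and cell cycle genes and higher enteroendocrine and tuft cell genes, as list medians, than the dsGFP control, by label. All 29 measured cell cycle genes were below 0, with a median of -1.21 and 21 at least 2-fold lower; Mcm7 was -2.24 and Mcm4 -2.02. CBC genes had a median of -0.96, with Olfm4 at -4.76, Cdca7 at -2.08, the ion cotransporter Slc12a2 at -2.05 and Lgr5 at -2.03, and Wnt targets one of -0.37, with the ephrin receptor gene Ephb3 at -2.33. Paneth genes had a median of -1.19, with Ang4 at -2.72 and the alpha-defensin gene Defa21 at -1.95. Tuft cell genes had a median of 1.04, with the lipoxygenase gene Alox5 at 1.33, while among enteroendocrine genes (median 0.32) Gcg was 4.45 and Gip 3.78, beside Neurog3 at -1.03 and Pax4 at -1.41.

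Beside Sst (3.03), the highest named ratios were those of Kbtbd11 (4.19), Pcp4l1 (2.93), the lipase inhibitor Angptl4 (2.67), C1qtnf12 (2.56), the carboxylesterase Ces1g (2.55), Odf3b (2.52), glycogen phosphorylase Pygl (2.47), the retinol carrier Rbp4 (2.33) and Otop3 (2.24). With Mcm7 and Slc12a2, the lowest were Cdc42ep1 (-2.51), the antiviral membrane protein gene Ifitm3 (-2.48), the Hedgehog transducer Smo (-2.25), the angiogenin family members Ang2 (-2.23) and Ang6 (-2.12), the histone gene H2ac13 (-2.12), Uhrf1 (-2.04) and the mitotic kinesin Kif20a (-2.03). Interferon response genes (0.26) lay above the random range, and Notch (-0.23), position 4 (-0.41) and fetal and regenerative genes (-0.21) below it. Enterocyte (0.07), goblet (0.16), cholesterol synthesis (0.09) and p53 and stress genes (-0.03) lay within it. Of 569 genes at or beyond 2-fold, 195 were higher and 374 lower; the scanner's log ratio gave 963 higher and 896 lower, and 676 and 726 came from the authors' deposited table.

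This array resembled the array labelled Ascl2 overexpression of the same experiment. They shared 98 genes at least 2-fold higher and 73 lower, against 1.99 and 3.38 for independent lists, with 2 genes in opposite directions (r = 0.57). Unchanged genes with a shared control gave simulated correlations of 0.06 and 0.50, for no control noise and for a control share of 0.5 of the variance, and the covariance exceeded the simulated one by 0.07 and 0.05. The Tcf7l2 null array instead ran against it: r = -0.38 after the dye term and -0.15 before it, with simulated values of 0.17 and 0.53 and covariance differences of -0.05 and -0.07. In that pair 30 genes were beyond 2-fold in opposite directions, against 1.67 for independent lists, while 2 were higher and 5 lower on both. The labels give both arrays the same dye orientation and the conditions could oppose, so the direction was kept. The dsGFP control cannot be split, so part of any resemblance within experiment 2 may come from it.

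Setting the Tcf7l2 null array with Ascl2 overexpression against the one without it asks what Ascl2 adds when Tcf7l2 is absent; the dye term and the control cancel. By label, every measured cell cycle gene was lower with Ascl2, with a median difference of -1.74 and 27 of 29 at least 2-fold lower. CBC genes had a median of -1.48, with 15 of 23 at least 2-fold lower, among them Olfm4 (-5.89), Slc12a2 (-2.74) and Lgr5 (-2.60). Paneth (-0.91), Wnt target (-0.44), Notch (-0.55) and fetal and regenerative genes (-0.52) were lower, while enterocyte (0.67, with Fabp2 at 1.72 and Rbp2 at 1.62), tuft (1.08) and enteroendocrine genes (0.31) were higher.

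Named genes with the highest differences were Kbtbd11 (4.49), Me1 (3.30), Ces1g (3.26), Pcp4l1 (3.21), Slc16a9 (3.19), Odf3b (3.15), Bdh2 (3.05), Ggt1 (2.95) and Angptl4 (2.82). Sst was also higher and was not well above background in the Tcf7l2 null RNA, so no fold is given. The lowest were Ctrb1 (-4.03), Cdc42ep1 (-3.45), Mcm7 (-3.03), Ifitm3 (-3.01), H1f5 (-2.97), C4bp (-2.91), H2ac23 (-2.84), Tipin (-2.74) and Slc12a2, and Epdr1, also lower, was not well above background with Ascl2 overexpression. In all, 1480 genes were at or beyond 2-fold, 556 higher and 924 lower; the scanner's log ratio gave 1882 and 1839, and 1231 and 1374 came from the authors' deposited table. These differences correlated with the effect of Ascl2 overexpression in experiment 1 at r = -0.54 across genes. The subtracted Tcf7l2 null array itself correlated with experiment 1 at 0.58, and the array with Ascl2 overexpression at -0.35. The value of -0.54 therefore comes in part from the subtracted array. Exchanged labels within experiment 2 could give it too, so it does not show what Ascl2 adds.

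**Figure D2:**
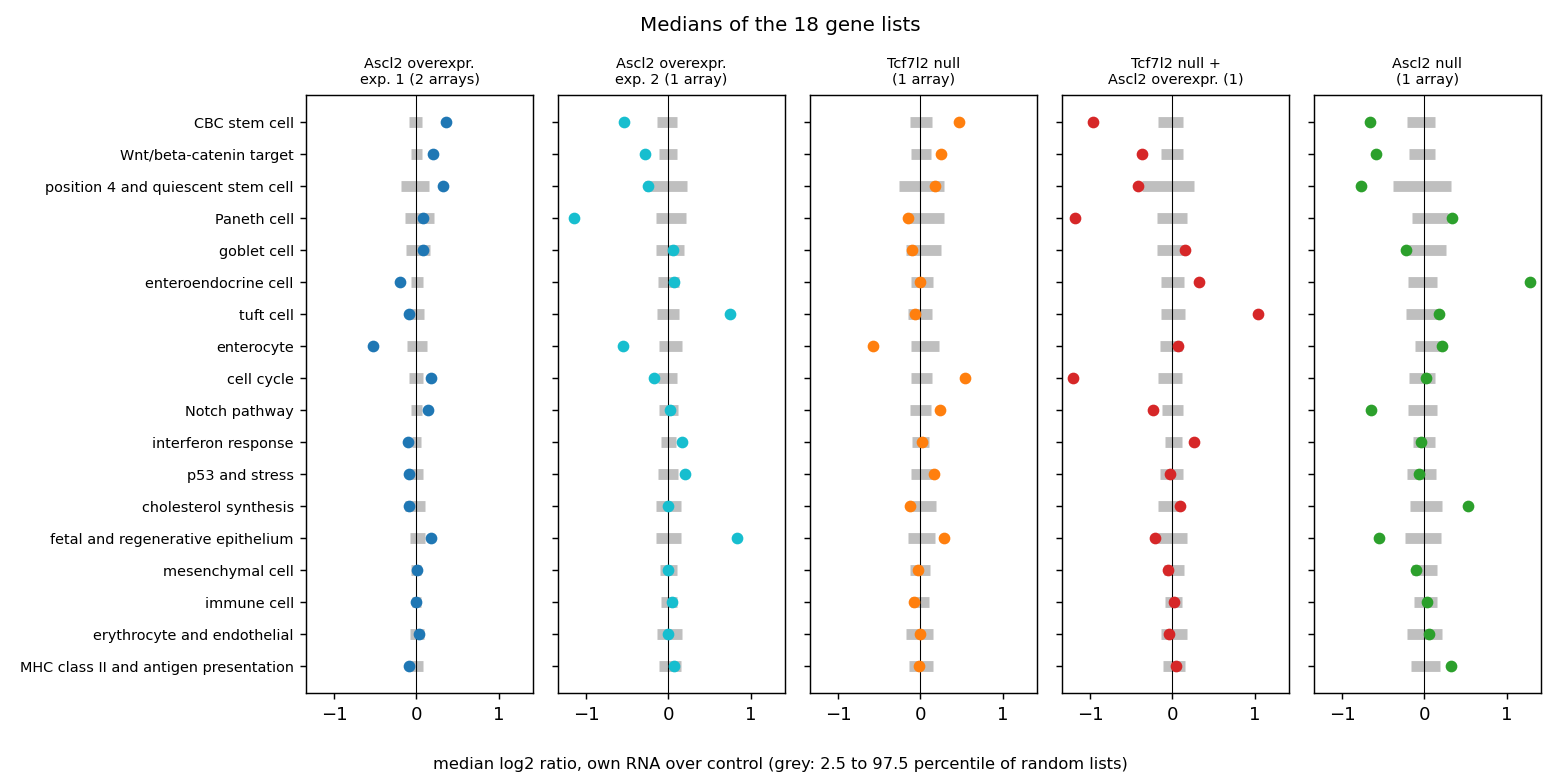
Median log2 ratio of own RNA over control (horizontal axes) of each of the 18 gene lists (vertical axis), by array label. Coloured points are list medians and grey bars the central range of random lists; the cell cycle median lies at 0.54 for Tcf7l2 null and at -1.21 with Ascl2 overexpression added.

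On the array labelled Ascl2 null, the enteroendocrine list had a higher median, with members going both ways, while stem cell and Notch pathway genes were lower than in the VillinCreERT2 control. The enteroendocrine median was 1.29, with 12 of 21 members at least 2-fold higher and 4 at least 2-fold lower. Gcg was 5.03, Gip 4.31, Cck 4.03, neurotensin (Nts) 3.91 and the granule protein gene Chga 1.98, whereas Pax4 was -3.34, Insm1 -2.38, Neurog3 -2.33 and Rfx6 -1.48; Nkx2-2 was 1.01 and Sct -0.19. CBC genes had a median of -0.66, with 19 of 22 below 0, led by Olfm4 (-2.90) and the sodium channel subunit Scn2b (-1.28), and Lgr5 was -0.64. Notch pathway genes had a median of -0.65, with the fringe gene Mfng at -2.41 and the ligand Dll1 at -1.74. Cck, Nts, Chga, Neurog3, Rfx6, Nkx2-2, Sct and Dll1 were named after their values were seen.

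Wnt targets had a median of -0.59, with Apcdd1 at -1.92 and Ccnd1 at -1.28, but the Wnt-induced factor Sp5 was 4.11. Position 4 and quiescent stem cell genes (-0.77), fetal and regenerative genes (-0.55) and goblet genes (-0.22) were also below the random range. MHC class II and antigen presentation genes (0.32) lay above it. Cholesterol synthesis (0.53), Paneth (0.34) and enterocyte genes (0.21) had medians above 0, which became -0.05, -0.19 and -0.45 with median centring. On the self-self array of this slide the Paneth median was already 0.42, the goblet median 0.21 and the fetal and regenerative median -0.26. The cell cycle median was 0.02, tuft 0.18, interferon response -0.04 and p53 and stress -0.06. Lists of other cell types stayed near 0: mesenchymal -0.10, immune 0.03, and erythrocyte and endothelial 0.05 here, and between -0.07 and 0.04 on the 3 arrays of modified organoids in experiment 2, where the self-self array gave -0.14 for erythrocyte and endothelial genes.

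Named genes with the highest ratios were Tmem37 (5.03), monoamine oxidase Maob (4.56), the immunoproteasome subunit Psmb8 (4.26), the transcription factor Nkx6-3 (4.12), Sp5, Rbp4 (3.90), Angptl4 (3.75), the myosin light chain gene Myl9 (3.51) and S100a6 (3.49), and Zfp503 was at least 9.77-fold higher. The lowest measured were Hoxd4 (-3.52), the primase subunit Prim2 (-3.50), Pax4, Pthlh (-2.55), Dusp26 (-2.43), Mfng and Insm1. Eif2s3y, a gene of the Y chromosome, was at least 13.0-fold lower, Khdc1a at least 6.33-fold and the Y-linked Rbmy at least 4.62-fold. In total 732 genes were at or beyond 2-fold, 430 higher and 302 lower, beside 82 on the self-self array of the same slide. Median centring gave 246 higher and 1038 lower, beside 1063 genes on that self-self array; the scanner's log ratio gave 954 and 1053, and 887 and 996 came from the authors' deposited table. The CBC median was -1.03 with median centring, and Lgr5 was -1.02 with the dye term of the model with separate effects.

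**Figure D3:**
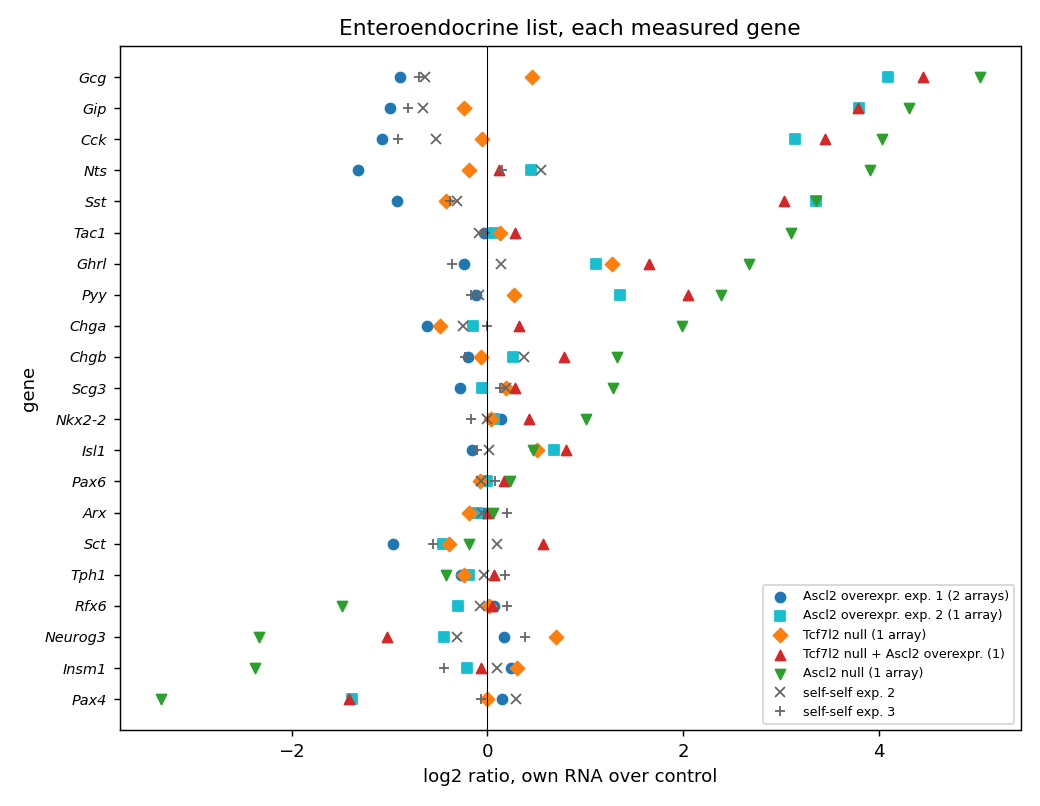
Log2 ratio of own RNA over control (horizontal axis) for each measured enteroendocrine gene (vertical axis, ordered by the Ascl2 null value). Each symbol is a label as given in the key; crosses and plus signs are the self-self arrays, and on the Ascl2 null array the genes run from Pax4 at -3.34 to Gcg at 5.03.

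Loss and overexpression of Ascl2 were set against each other on arrays that share no slide: the Ascl2 null array less its self-self array, and experiment 1. Of 15 genes beyond 2-fold in both, 13 went in opposite directions, against 0.80 for independent lists. This depends on the dye treatment: with the shared dye term in place of the self-self array, 22 genes were beyond 2-fold in both, 10 of them opposite, 7 higher in both and 5 lower in both (r = -0.29 over all genes). With the self-self array, in all 13 the gene was higher on the null array and lower with overexpression, among them alpha-fetoprotein (Afp, 5.08 and -1.53), Cck (4.74 and -1.08), Nts (3.79 and -1.32), Tmem37 (5.39 and -1.31) and Scin (1.38 and -1.52), named after their values were seen. Ptprz1 was higher on both, at 2.96 and 1.70. Before the dye term, and over the brighter spots rather than over genes, the Ascl2 null array and replicate 1 of experiment 1 correlated at -0.35. Replicate 2, with the dyes swapped, gave 0.10 as Cy5 over Cy3, so its opposition to the null array was weak. The labels state the dyes and the conditions could oppose, so the direction was kept. Over all genes r was -0.36 for experiment 1. With the overexpression array of experiment 2 in its place r was 0.25. In that pair 17 genes were opposite, 76 higher in both and 34 lower in both.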

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

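Of the tests in this part, those on labels, dye bias, shared shifts, the Y chromosome and intestinal position were chosen after the results were seen; the count over sign assignments was planned.

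For Ascl2 overexpression, 81 genes passed limma's test of the difference between experiments 2 and 1. That test sets the single array of experiment 2 against the spread of the experiment 1 dye swap and the self-self arrays, which is technical, so it cannot show a difference beyond the spread between cultures, and the list calls below share this limit. Experiment 2 minus experiment 1 was -2.66 on the log2 scale for Lgr5, 4.99 for Gcg, 4.79 for Gip, 4.22 for Cck and 4.28 for Sst. With the preset correlation, camera called 11 lists for this difference. Their median differences were -0.94 for CBC stem cell, -1.36 for Paneth, -0.42 for Wnt target, -0.34 for cell cycle and -0.22 for Notch genes. They were 0.47 for enteroendocrine, 0.81 for tuft, 0.61 for fetal and regenerative, and 0.25 for interferon response genes. For p53 and stress genes the value was 0.21, and for MHC class II and antigen presentation genes 0.13. No list held with an estimated correlation, but that version has only 2 degrees of freedom here. Its failures therefore do not show that correlation between genes explains the calls.

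The arrays of experiment 2 may carry each other's labels. Across genes, the Tcf7l2 null array correlated with experiment 1 more strongly than the Ascl2 overexpression array. The excess was at least 0.41 under 3 dye treatments. The CBC medians of these arrays, with the dye term shared by all arrays, were 0.47 and -0.42. The array labelled with both is in question too. Ascl2 overexpression less that array correlated with experiment 1 at 0.42, and that array less Tcf7l2 null at -0.54. In the first value the arrays carry dye terms of different models, so part of the difference between experiments remains in it. In the second the dye term cancels. Without a dye term, Ascl2 overexpression correlated with experiment 1 at 0.14 and the array labelled with both at -0.29. The Tcf7l2 probes leave the labels open, since the deleted region is unknown. The brightest was -0.39 on the array labelled Tcf7l2 null and 0.13 on the array labelled with both. It was 0.02 on the Ascl2 overexpression array, from the model with separate effects, and 0.42 and -0.49 on the self-self arrays. The dimmer 2 were -0.16 and -0.24 with the label Tcf7l2 null, and -0.20 and -0.26 with both. They were -0.07 and 0.09 on the Ascl2 overexpression array, with self-self ratios from -0.20 to 0.32. Dye bias of the slide is argued against, since the CBC median of the overexpression array less its self-self array stayed at -0.46, against a largest self-self median of 0.16. A shift common to the slide or its dsGFP control cannot be told apart. The difference between experiments correlated at -0.14 with the Tcf7l2 null array. That array was taken after the shared dye term, which holds part of the same difference, so a negative part is built in. With the dye term of the model with separate effects, its covariance was 0.035 with experiment 2 overexpression and 0.028 with experiment 1. The sign of -0.14 therefore rests on the dye term, and the value decides nothing about a shift. The bound of -0.3 for excluding a shift was set, in place of 0, after -0.14 was seen. The reason was that the null effect itself could offset a smaller shift. For CBC, Paneth and tuft genes, with differences of -0.94, -1.36 and 0.81, the Tcf7l2 null medians were 0.47, -0.15 and -0.07. A common shift would have to be largely offset there. The fetal and regenerative median there, 0.29, went the way of its difference, 0.61. The array labelled with both had CBC, Paneth and tuft medians of -0.96, -1.19 and 1.04. A real difference between the experiments, in control or time of extraction, stays open and untested.

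On the Ascl2 null array, 10 of the 12 genes on the Y chromosome that were well above background in the control were not so in the null RNA, against 3.71% of 17552 genes. That share was not matched on intensity. The folds of the 10 genes before the dye term ran from 1.28 to 13.0 (Eif2s3y), so some were lower by little. Among Y-linked genes measured in both RNAs, Zfy1 was -0.03 and the clone AK007945 -2.45. Dye bias is argued against by a median of -0.33 for the listed Y-linked genes on the self-self array, against -1.76 on the null array. These medians are rough. Of the listed genes, Uty was well above background in neither channel of the null array, and Ddx3y, Eif2s3y and Kdm5d only in its control channel. Null organoids that lack a Y chromosome would give this loss of Y-linked signal. Whether they came from a female animal or lost the chromosome cannot be told apart, since Xist was well above background only in the null RNA: its 1.53-fold difference before the dye term was measured against a control at background, so the true fold is unknown and the test set on it decides nothing. A difference of sex or culture would stand beside every Ascl2 null value given above.

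The enteroendocrine list had a median of 1.29 on the Ascl2 null array, with 15 of 21 members above 0 and 4 at least 2-fold lower. Dye bias is argued against by an enteroendocrine median of -0.11 on the self-self array, with 1.19 left on the null array after subtracting it. Organoids from different positions along the intestine could give such a pattern, but listed distal genes had a median of 0.60 rather than below 0, beside 1.97 for proximal genes. An effect of the loss of Ascl2 itself and the possible difference in sex stay open and untested.

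The count of genes for Ascl2 overexpression was 0 in all 4 sign assignments of the 3 arrays, the highest other being 0, and 4 assignments are too few for a share under 0.05.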

How the results depend on the processing

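Settings for the difference between experiments, for the list calls and for list medians other than CBC, and the dye term with separate effects, were added after the data were seen; the others were planned. Of the values that answer a comparison, 87 stayed within their spread or, for counts, within 1.5 times, 41 moved further and 1 reversed. Of the values for single genes and other lists, 13469 stayed within their spread, 1982 moved and 4 reversed. For genes and lists, a change of sign was counted only for values past their threshold or outside the range of random lists: the CBC median for Ascl2 overexpression, within that range, ran from -0.064 (no dye term) to 0.11 (a dye term per slide) and has no settled sign. Unless said otherwise, the cause was not tested.

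Ascl2 overexpression gave 0 genes without any 1 of its replicates and under all settings but 2: without the self-self arrays, and with the spread from its own arrays alone, 2 genes passed. They were Mybpc3 and Zfp467, and rest on replicate 2 of experiment 1, whose values were -9.49 and -6.69 beside values between -0.11 and 0.10 on the other overexpression arrays; they were named after their values were seen. The list calls fell from 4 to 2 with probes well above background on all 8 arrays and rose to 5 without the filter on dim probes and to 6 with median centring or the authors' table. Each ratio already sets an array's own RNA against control RNA on the same array. No further pairing across groups was possible because the groups compared share fewer than 2 replicate numbers.

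The 81 genes of the difference became 200 with offset 10 (81 shared), 180 without a dye term (77 shared), 146 in the authors' table (65 shared) and 0 with median centring. Similar totals did not mean the same genes: 97 with the scanner's ratio shared 50, 94 with probes well above background on all 8 arrays shared 64, and 90 with the mean of probes shared 68.

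At 1.5-fold the counts were 1030 for Tcf7l2 null, 1713 with Ascl2 overexpression, 3696 for the difference of these arrays and 2243 for Ascl2 null. With the scanner's log ratio they were 1442, 1859, 3721 and 2007, and from the authors' values 942, 1402, 2605 and 1883; both also raised the self-self counts, to 720 and 1157, and to 286 and 1058. A limma test with pooled spread gave 0, 0, 0 and 181. That test sets 1 array against the spread of other arrays, which may be technical, and says nothing about the spread between cultures. Tcf7l2 null gave 184 genes without a dye term and 219 with a dye term per slide, and Ascl2 null 1284 with median centring.

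CBC medians moved to 0.63 (scanner's ratio) and 0.30 (separate effects) for Tcf7l2 null. With Ascl2 overexpression they were -1.16 (offset 10), -1.20 (scanner's ratio), -0.73 (mean of probes) and -1.23 (authors' table), and for the difference -1.88, -1.93, -1.19 and -2.05, and -1.77 with median centring. For Ascl2 null they were -0.48 (scanner's ratio), -1.03 (median centring) and -0.48 (mean of probes).

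Between Ascl2 null and overexpression, 179 genes were opposite at 1.5-fold, and the correlation reversed to 0.25 with the experiment 2 array. With median centring the Ascl2 null medians of Paneth (-0.19), enterocyte (-0.45) and cholesterol genes (-0.053), and the cell cycle median for overexpression (-0.0054), changed sign. Signal over background limits dim genes, which have bounds only.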

Other observations

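The values in this part were described after they were seen, without a test. On the array labelled Ascl2 null, the calcium carrier S100g was 2.93 and the iron exporter Slc40a1 1.85. The array labelled Ascl2 overexpression of experiment 2 had 1.85 for S100g and 2.75 for Slc40a1, while experiment 1 gave -0.62 and 0.13.

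Members of the interferon response list went both ways. The immunoproteasome genes Psmb8 and Psmb9 were 4.26 and 1.47 on the Ascl2 null array and 2.04 and 1.12 on the array labelled Tcf7l2 null with Ascl2 overexpression, whereas the chemokine gene Cxcl10 was -1.95 on the Ascl2 null array. Oas1a was 2.28 there. Among enterocyte genes on the Ascl2 null array, the alkaline phosphatase Alpi was 2.44 and the apolipoproteins Apoa4 and Apoa1 were 1.99 and 1.48, while Dpp4 was -0.79.

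Overlaps of genes at least 2-fold higher also joined the Ascl2 null array with arrays of experiment 2 that have another control. With Tcf7l2 null and Ascl2 overexpression combined it shared 95 such genes, and 47 at least 2-fold lower, against 4.33 and 5.86 for independent lists, with 12 in opposite directions. With Tcf7l2 null alone it shared 4 and 4, and 43 genes went in opposite directions, against 2.17.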
